A study of Homo sapiens with 12 samples.

How the data were processed

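Biotin-labelled total RNA of H9 human embryonic stem cells (passages 28 to 35), extracted with TRIzol per the labels' protocols, was read on 12 arrays in 4 groups of 3. Groups and replicate numbers were taken from the sample titles. Undifferentiated cells were grown in mTeSR on a basement membrane matrix and differentiating cells in DMEM/F12 with 15% serum, per the labels' protocols. The deposited values are linear probe set intensities. How the authors corrected background, summarised probes and scaled arrays is not given in the sources used here. After leaving out the lowest and highest 2% of probe sets, the mean of the deposited intensities was 500 on each array, as after scaling to a target, so only signal relative to the rest of an array is compared. The median was 64.2 to 78.0, and 23.1% to 26.5% of probe sets per array lay under 16.

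Of 54675 probe sets, 42898 were listed in the platform's annotation, 41097 with a single gene symbol, 1801 with several and 11777 not listed here. Symbols were updated through the gene ID where the human reference table of assembly GRCh38.p14 held it, for 41043 probe sets, and none of its coordinates were used. No gene was named from a probe set with several symbols. Each of 19775 genes was represented by the single-symbol probe set with the highest mean log2 value over the 12 arrays. That choice can decide the direction where probe sets of a gene disagree, as for NR6A1. In other named genes the only other probe set went the other way without being called. Examples are ZDHHC22 and HOXB1 with Dox at d0, NEFM between the day 6 groups, and HOXB3 and DLX2 from d0 to RA-labelled arrays. Of 2 other probe sets of NODAL, 1 went its way with Dox at d0 and none was called against it. Values were tested as log2(intensity + 16), which understates the change of dim genes. Where a group mean lay under 16 (among named genes CYP24A1, PRDM14, RMST, SP5, HOXB1, HOXB3, HOXA2, FGF8, DLX2, DAZL, FOXD3 and VWF in some comparisons), the size of the log2 fold change depends on that pseudocount. It also does where a mean lay little above 16. Examples are LIX1 at d0 (20.0) and NR5A2 (23.7), GFRA1 (21.5) and RARRES2 (16.1) in day 6 arrays labelled retinoic acid. The tests were limma's lmFit and eBayes (limma 3.58.1, R 4.3.3) on all 12 arrays with a mean per group and 8 residual degrees of freedom, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. p-values for probe sets of NR6A1 and the POU5F1 family were adjusted over all 54675 probe sets. Log2 fold changes are differences of group means on that scale, and folds their antilogs.

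The comparisons were d0 with Dox against d0, Dox-labelled against RA-labelled day 6 arrays, RA-labelled against d0, and Dox-labelled day 6 against d0 with Dox. Before the data were examined, the tests, alternatives, 22 gene lists (457 genes, of which 407 had a probe set of their own) and the rule for named genes were fixed. The rule took NR6A1, POU5F1, and, among called genes whose arrays did not overlap and whose higher group mean was at or above the median gene, the 8 largest rises and 8 largest falls in the first 2 comparisons and 5 each in the others. It also took up to 2 largest rises and 2 largest falls of each list described, or the smallest p where none passed. Lists were tested with limma's camera at a preset correlation of 0.01 and adjusted over the 22 lists, and again with an estimated correlation and with fry, which asks whether a list's genes move 1 way without comparing them with other genes. For d0 with Dox against d0 the pluripotency and WNT calls held with an estimated correlation and the retinoic acid, epithelium and stress calls did not. List counts are given over all genes tested and adjusted over the list alone.

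The procedure was tested on simulated data of 19775 genes for d0 with Dox against d0. At each size 50 genes were changed, drawn only from those at or above the median mean. Limma recovered 12 at 1.25-fold, 34 at 1.5-fold, 49 at 2-fold and 50 at 4-fold, with 7 false calls among 19555 unchanged genes. Recovery of dimmer genes was not measured. A planted list was called and 0 of 21 unchanged lists were. The simulated genes varied independently, so this does not test list calls among correlated genes. Alternatives were quantile normalization, median centring, the mean of a gene's probe sets, all probe sets, genes above the median mean, a trended robust variance, array weights, the 6 arrays of a comparison alone, the replicate number as a block, a 2-fold minimum, a pseudocount of 1, and leaving out each array. RNA quality was described by ratios of 3' to 5' probe sets of ACTB and GAPDH. Probe sets without a single gene name, among them those of the 62 control probe sets that carry none, were left out of the gene tests, and no scan dates or scanner files were analysed here, so array batches were not tested.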

Results

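RNA from H9 cells, an established line of human embryonic stem cells, was measured on 12 oligonucleotide arrays, each reading 54675 probe sets. The cells carried a construct that switches on GCNF, an orphan nuclear receptor encoded by NR6A1 and known as a repressor of pluripotency genes, when doxycycline (Dox) is added. The 4 groups held 3 arrays each: untreated undifferentiated cells (d0), undifferentiated cells given 1 µg/ml Dox for 4 days (d0 with Dox), and cells in a serum medium for 6 days with either 1 µM retinoic acid or 1 µg/ml Dox. The median signal per array lay between 64.2 and 78.0, and the number of arrays limits the precision. Replicate arrays correlated at r = 0.986 to 0.988 on the log2 scale, and no pair held identical values. The labels call the replicates biological without saying how the cultures were separated, so p-values measure the spread between these arrays. Rose and fell are used below of genes past an adjusted p of 0.05 in limma. Signals are given as mean ± SD and log2 fold changes ± SE, with n = 3 arrays per group.

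NR6A1 was read by 7 probe sets, which checked the induction and the labels. In undifferentiated cells all 7 were higher with Dox. The most induced of 4 designed from an mRNA or genomic record went from 26.8 ± 17.6 to 615 ± 40.8, a log2 fold change of 3.96 (adjusted p = 6.36e-05 over all probe sets), and the next from 119.8 ± 21.1 to 665 ± 104. Another of them, near the signal floor, did not pass (1.54, adjusted p = 0.087). The 3 probe sets designed from expressed sequence tags (ESTs) were already bright at d0 and rose less. The brightest, which represents the gene here, went from 1457 ± 115 to 2869 ± 269.9 (log2 fold change 0.97, adjusted p = 0.00437).

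At day 6, 3 of the 4 mRNA-derived probe sets went against the labels. The most induced stood at 336 ± 70.9 in the arrays labelled retinoic acid and 29.2 ± 13.7 in those labelled Dox. The next 2 by induction were also lower in the latter (log2 -1.61 and -1.21), and the dim one did not pass (-0.17, adjusted p = 0.869). The EST-derived ones ran the other way, the brightest standing at 528 ± 37.8 and 1009 ± 223 (log2 0.89, adjusted p = 0.0026), so the direction of NR6A1 at day 6 depended on the probe set. Which part of the gene each probe set reads, and so whether it detects the construct, is not given in the sources used here. Enzymes that degrade retinoic acid and are induced by it, CYP26A1 and CYP26B1, were far brighter in the arrays labelled Dox. The day 6 groups are therefore called the RA-labelled and Dox-labelled arrays throughout, and every direction drawn from them rests on those labels.

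POU5F1, the pluripotency factor OCT4, had no probe set of its own. A probe set shared by POU5F1 and 3 near-identical copies read 14001 ± 876 at d0 and 7959 ± 56.5 with Dox (log2 fold change -0.81, adjusted p = 0.00039). It read 901 ± 46.4 and 337 ± 14.5 in the RA-labelled and Dox-labelled day 6 arrays (log2 -1.38 for Dox-labelled against RA-labelled, -3.93 for RA-labelled against d0 and -4.50 for Dox-labelled against d0 with Dox). Its assignment to POU5F1 is uncertain, and it entered no list test. Probe sets assigned to single copies were also lower with Dox at d0, POU5F1P4 (-1.21), POU5F1P3 (-0.97) and POU5F1B (-0.65). At d0 they read 15094, 11554 and 21045, in the range of the shared probe set. Since the copies are near-identical, signal from POU5F1 itself cannot be told apart in them. They are no separate support for its fall and do not show that the copies are expressed. These copies were named after their values were seen.

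**Figure D1:**
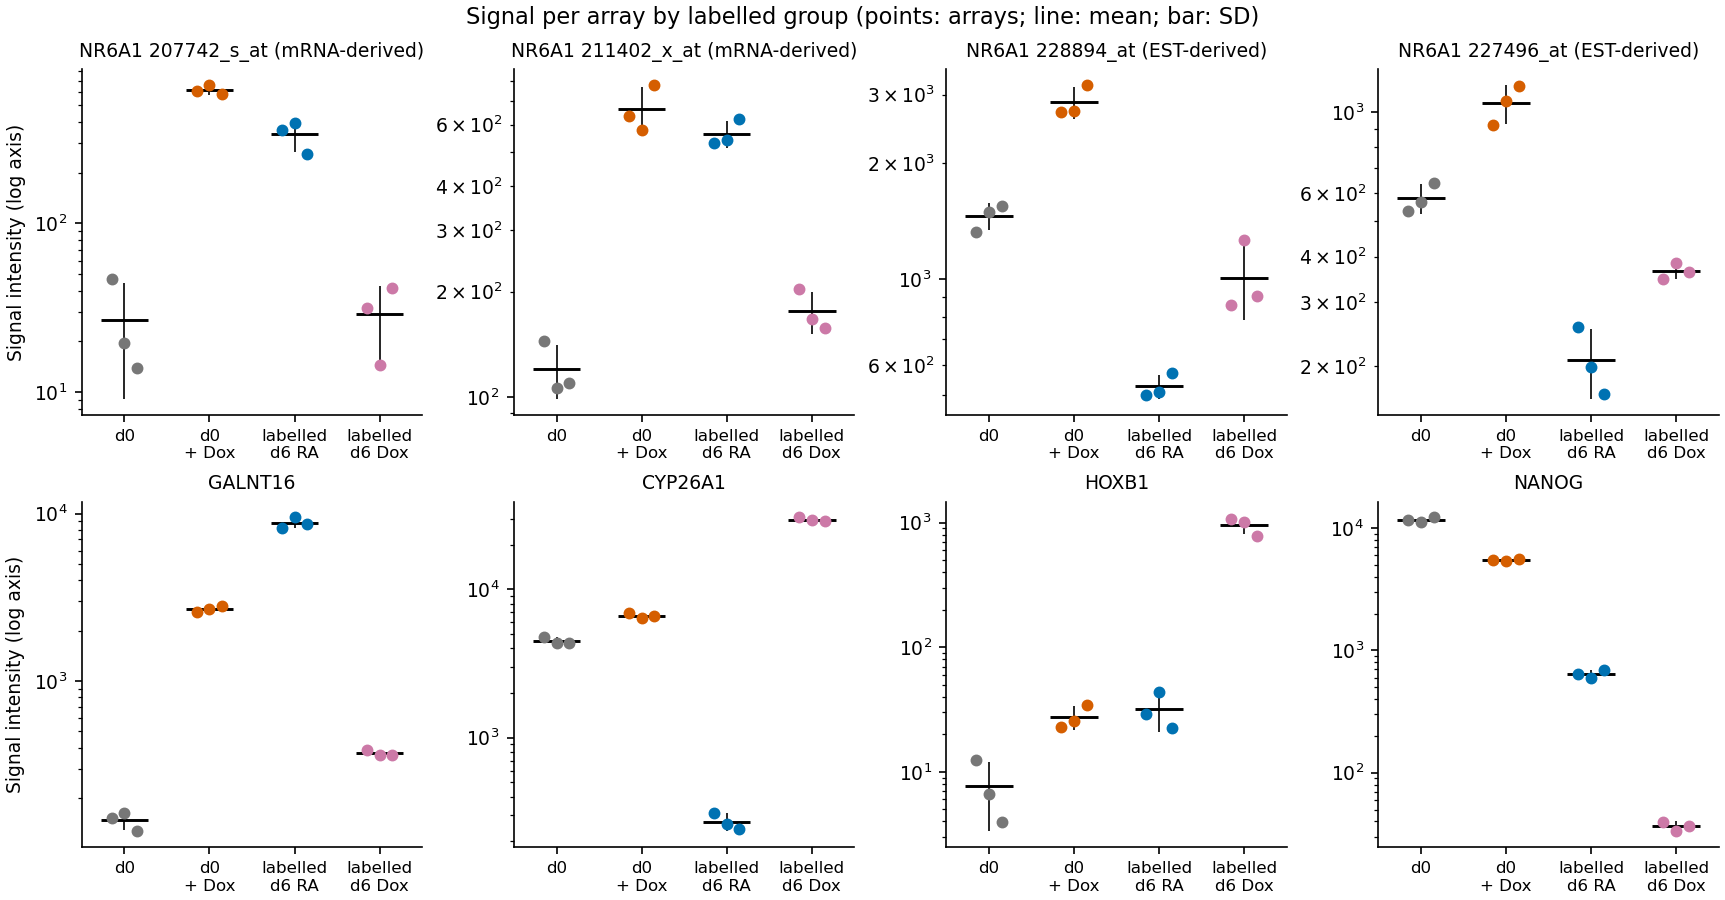
Signal intensity (log axis) of 4 NR6A1 probe sets and of GALNT16, CYP26A1, HOXB1 and NANOG on each of the 12 arrays, by labelled group; points are arrays, lines means and bars SD. The mRNA-derived NR6A1 probe sets shown and GALNT16 were high in d0 with Dox and in the RA-labelled day 6 arrays, and CYP26A1 (29594 in the mean) and HOXB1 were highest in the Dox-labelled ones.

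The comparison of d0 with Dox against d0 asked what GCNF changes in undifferentiated cells. With Dox the pluripotency list lay lower and the WNT response list higher. NODAL, a TGF-beta family ligand that sustains human pluripotency, fell from 4240.0 ± 305 to 567 ± 34.7 (log2 fold change -2.87 ± 0.26, adjusted p = 9.99e-05), and NANOG, a core pluripotency factor, fell from 11672 ± 556 to 5468 ± 111 (-1.09 ± 0.08, adjusted p = 2.05e-05). GALNT16, an enzyme of O-glycosylation, rose most among the named genes, from 148 ± 18.7 to 2694 ± 115 (4.05 ± 0.09, adjusted p = 3.01e-08). In all 2552 of 19775 genes were called (12.9%), 1532 higher and 1020 lower (1203 and 1025 after centring each array on its median), of which 226 and 139 changed at least 2-fold. The arrays of the groups did not overlap for 31.5% of genes, where chance gives 10% for 3 against 3.

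Other large rises were LIX1 (14.5-fold), PKDCC, a secreted kinase of matrix proteins (559 ± 75.5 to 6082 ± 201), the neuronal leucine-rich repeat gene LRRN3 (9.88-fold) and the homeobox gene MEIS2 (8.66-fold). Next came PRTG, an immunoglobulin-type receptor of the early nervous system (849 ± 100.4 to 6843 ± 210.1), the neuronal membrane gene SLITRK5 (7.64-fold), and ZEB2, a repressor of E-cadherin (7.15-fold). Adjusted p of these rises lay between 3.01e-08 and 5.00e-05. Falls beside NODAL were the noncoding RNA LINC01844 (-2.42 on the log2 scale), DACT1, a modulator of WNT signalling (3325 ± 120.4 to 610.5 ± 51.6), the G protein subunit GNA14 (-2.10) and ZDHHC22 (-1.93). Then came the methyltransferase TMT1A (-1.80), HEY2, a transcriptional repressor downstream of Notch (-1.72), and the secreted ligand PROK2 (-1.70, adjusted p = 0.0238). For each of these 16 genes the 3 arrays of the higher group lay above the 3 of the lower, as the rule that named them required.

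Pluripotency genes divided. Of 30 measured, 4 rose, 13 fell and 13 did not pass (7 and 18 when adjusted over the list alone). After NODAL, GDF3, another TGF-beta family ligand, fell most (-1.34 ± 0.23, adjusted p = 0.00437). Against this OTX2, a factor of the primed state and of anterior ectoderm, rose from 2526 ± 87.8 to 4472 ± 159.9 (0.82) and SFRP2, a secreted WNT inhibitor, rose 1.33-fold. As a whole the list lay below other genes (camera adjusted p = 3.10e-05, adjusted p = 0.0129 with an estimated correlation). Among 10 measured genes reported as GCNF targets in the mouse, 2 rose, 1 fell and 7 did not pass (2 and 2 when adjusted over the list alone): SOX2 (0.35) and GPD2 (0.33) were the rises and NANOG the fall, with no call for the list from camera (camera adjusted p = 0.476) and a downward call from fry (adjusted p = 0.00196). This list and the pluripotency list share NANOG, SOX2 and DNMT3B among others, so their calls are not independent in any comparison. SOX2 missed the threshold without any single array of these 6 (log2 fold changes of 0.32 to 0.38).

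The WNT response list lay higher. DKK1, a secreted WNT inhibitor, went from 343 ± 41.0 to 2164 ± 80.4 (2.61 ± 0.10, adjusted p = 4.72e-07) and SFRP1, another WNT inhibitor, from 5264 ± 263 to 20417 ± 1022. Of 13 measured, 4 rose, 0 fell and 9 did not pass (6 and 0 when adjusted over the list alone). The shift of the list was called (camera adjusted p = 6.09e-05, adjusted p = 0.0147 with an estimated correlation). Retinoic acid response genes lay higher (camera adjusted p = 0.011), a call that was lost when the correlation between genes was estimated (adjusted p = 0.0964 with an estimated correlation). No retinoic acid was in the medium as labelled. Of 19 measured, 7 rose, 2 fell and 10 did not pass (8 and 4 when adjusted over the list alone). MEIS2 and the retinoic acid binding protein CRABP2 (1.24) led the rises, and RARRES2, which encodes the adipokine chemerin (-0.99), and the transglutaminase TGM2 (-0.45) fell. Of 28 HOX genes measured, 1 rose, 0 fell and 27 did not pass (1 and 0 when adjusted over the list alone), HOXB1 at a low signal (7.68 ± 4.33 to 27.5 ± 5.97).

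Epithelial genes lay lower. Of 20 measured, 0 rose, 6 fell and 14 did not pass (0 and 9 when adjusted over the list alone), led by RAB25, a GTPase of epithelial trafficking (-1.18), and the tight junction gene CLDN7 (-1.02). Their camera adjusted p was 0.000961, against adjusted p = 0.342 with an estimated correlation. Mesenchymal and matrix genes went both ways. In 26 measured, 6 rose, 5 fell and 15 did not pass (10 and 5 when adjusted over the list alone); ZEB2 and ZEB1 (1.66), repressors of epithelial genes, rose, while the surface glycoprotein THY1 (-0.80) and fibronectin, FN1 (-0.50), fell (camera adjusted p = 0.611). Neural crest genes counted 6 rises, 1 fall and 8 not passing (6 and 1 when adjusted over the list alone) of 15, with SOX5 (1.57) and TFAP2A (1.39) up and ETS1 down (-1.31); the list missed the threshold (camera adjusted p = 0.0649). It passed without replicate 2 of d0 (0.0177), without replicate 1 of d0 with Dox (0.0248), with quantile normalization (0.0497) and with median centring (0.0283). Among 24 neural genes 5 rose, 1 fell and 18 did not pass (5 and 2 when adjusted over the list alone), LHX2 (1.71) and MAP2 (1.65) rising and TUBB3 falling (-0.30; camera adjusted p = 0.208).

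Integrated stress response genes lay lower (camera adjusted p = 0.00772), a call that fry shared (adjusted p = 0.000744) and that camera lost in another setting (adjusted p = 0.0964 with an estimated correlation). Of 21 measured, 2 rose, 8 fell and 11 did not pass (2 and 10 when adjusted over the list alone); STC2 (-0.77) and the stress factor ATF3 (-0.59) fell, and DDIT4, an inhibitor of mTORC1 (0.77), and the cystine transporter SLC7A11 (0.48) rose. BMP and TGF-beta response genes went both ways. Of 16 measured, 4 rose, 3 fell and 9 did not pass (4 and 3 when adjusted over the list alone): the BMP-induced repressors ID4 (888 ± 81.7 to 3419 ± 234) and ID3 (2452 ± 191 to 7366 ± 124) rose and PMEPA1 (-1.27) and SMAD7 (-1.11), inhibitors induced by TGF-beta, fell. The list's median was -0.12 and its mean 0.12, and camera found no shift (adjusted p = 0.955).

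Camera called no other list, at adjusted p of 0.208 or more. Fry, which asks only whether members move 1 way and not whether they differ from other genes, put up the DNA methylation and corepressor list (adjusted p = 9.34e-05), and of those above also the neural crest (0.000643), neural (0.00562) and mesenchymal (0.00773) lists. In the primitive streak list 1 rose, 1 fell and 12 did not pass (1 and 1 when adjusted over the list alone) of 14, APLNR up (1.94) and FGF8 down (-1.52). Cardiac and lateral mesoderm genes counted 1 rise, 2 falls and 15 not passing (1 and 2 when adjusted over the list alone) of 18, with BMP4 (1.08) against MYL7 (-0.60) and ACTC1 (-0.42). Of 21 endoderm and liver genes 0 rose, 1 fell and 20 did not pass (0 and 1 when adjusted over the list alone), CXCR4 being the fall (-0.69). Trophoblast and amnion genes counted 2 rises, 1 fall and 19 not passing (2 and 1 when adjusted over the list alone) of 22. GATA3 (0.84) and MSX2 (0.72) stood against IGFBP3 (-0.80). The germ cell gene DAZL rose from 309 ± 69.3 to 992 ± 64.2 (1.65 ± 0.30, adjusted p = 0.00616), in a list of 19 with 1 rise, 0 falls and 18 not passing (1 and 0 when adjusted over the list alone). Endothelial and blood genes counted 2 rises, 1 fall and 14 not passing (2 and 1 when adjusted over the list alone) of 17. They were the receptor TEK (1.67) and low-signal VWF (1.16) against the receptor KDR (-0.87). Proliferation genes counted 2 rises, 3 falls and 24 not passing (2 and 3 when adjusted over the list alone) of 29. TYMS (0.37) and CCND2 (0.33) stood against CCNE2 (-0.60) and CDC6 (-0.56). Of 15 p53 response genes 1 rose, 2 fell and 12 did not pass (2 and 2 when adjusted over the list alone). TP53I3 (0.41) stood against RRM2B (-0.62) and MDM2 (-0.43). Hypoxia and glycolysis genes counted 3 rises, 2 falls and 13 not passing (3 and 2 when adjusted over the list alone) of 18. PFKFB4 (0.84) and ADM (0.41) stood against PDK1 (-0.84) and BNIP3 (-0.34). Cholesterol synthesis showed 0 rises, 1 fall and 11 not passing (0 and 1 when adjusted over the list alone) of 12, DHCR7 (-0.49). DNA methylation and corepressor genes counted 3 rises, 1 fall and 11 not passing (6 and 2 when adjusted over the list alone) of 15. TET2 (0.58) and UHRF1 (0.32) stood against TET1 (-0.45). The endoderm, cardiac, proliferation, p53 and hypoxia lists had a median and mean above 0 and a camera direction below it, and the endothelial list a mean above 0 with median and camera below.

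With these gene groups moved a mark of RNA quality: the ratio of 3' to 5' ACTB probe sets was 3.24 ± 0.139 at d0 and 3.86 ± 0.0111 with Dox, and that of GAPDH 1.53 ± 0.0577 and 1.62 ± 0.0554. No Dox-treated cells without the construct were analysed here, so an effect of Dox itself is not separated from that of GCNF. Fitted on the 6 arrays alone, 1522 genes were called.

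The comparison of Dox-labelled with RA-labelled day 6 arrays asked what GCNF changes in differentiating cells relative to retinoic acid. The retinoic acid response list was higher in the arrays labelled Dox, against the label, and the proliferation list was higher as well. CYP26A1 stood at 271 ± 37.0 in the RA-labelled and 29594 ± 1005 in the Dox-labelled arrays (104-fold; log2 fold change 6.70 ± 0.09, adjusted p = 2.65e-10), and CYP26B1 went from 46.6 ± 11.9 to 5075 ± 346 (6.36 ± 0.23, adjusted p = 8.65e-08). NANOG was lower in the Dox-labelled arrays, 36.7 ± 3.28 against 639.8 ± 46.0 (-3.64 ± 0.08, adjusted p = 2.48e-09). In all 5120 of 19775 genes were called (25.9%), 2713 higher and 2407 lower in the Dox-labelled arrays (2768 and 2056 after median centring), of which 764 and 380 differed at least 2-fold.

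Beside the CYP26 enzymes, the largest rises were RARRES2 (16.1 ± 2.66 to 1325 ± 109), the nuclear receptor NR5A2 (38.6-fold) and the noncoding RNA LINC02381 (35.4-fold). GFRA1, a coreceptor for GDNF, followed (30.8-fold, from 21.5 ± 23.0, near the signal floor). So did CYP24A1, which degrades vitamin D (13.8 ± 9.08 to 869.6 ± 98.6, from under the pseudocount), and the cannabinoid receptor CNR1 (85.3 ± 12.5 to 2655 ± 222). Adjusted p of these rises was at most 1.54e-05. The largest falls were a precursor transcript annotated as MIR302B, of a microRNA cluster of pluripotent cells (6864 ± 602 to 275 ± 5.36; the mature microRNA was not measured), GALNT16 (8816 ± 643 to 370.2 ± 13.4), the BMP antagonist GREM1 (11168 ± 256 to 645 ± 129) and NANOG. They were followed by the neuronal adhesion gene NEGR1 (-3.48), PSG1, of a family of near-identical placental glycoproteins whose signals a probe set can share (-3.38), the pluripotency factor PRDM14 (266 ± 20.2 to 14.1 ± 6.44, to under the pseudocount) and SLITRK5 (-3.03). GALNT16 and SLITRK5 were also among the largest rises with Dox at d0.

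Retinoic acid response genes counted 17 rises, 0 falls and 2 not passing (17 and 0 when adjusted over the list alone) of 19 (camera adjusted p = 1.80e-18, adjusted p = 0.00041 with an estimated correlation). HOX genes counted 10 rises, 0 falls and 18 not passing (11 and 0 when adjusted over the list alone) of 28 (camera adjusted p = 0.000413, adjusted p = 0.0284 with an estimated correlation). Among the latter HOXB1, a direct retinoic acid target of the hindbrain, went from 31.8 ± 10.9 to 956 ± 149.9 and HOXA2 rose by 3.91 on the log2 scale. BMP and TGF-beta response genes lay higher. Of 16, 11 rose, 2 fell and 3 did not pass (11 and 2 when adjusted over the list alone), the activin subunit INHBA (2.56) and MSX2 (2.31) rising and CCN2 (-0.39) and PMEPA1 (-0.30) falling (camera adjusted p = 7.00e-06, adjusted p = 0.0331 with an estimated correlation). Of 29 proliferation genes 23 rose, 0 fell and 6 did not pass (25 and 2 when adjusted over the list alone), led by topoisomerase TOP2A (898 ± 88.6 to 2577 ± 252) and cyclin CCNB2 (1.41; camera adjusted p = 9.90e-13, adjusted p = 0.0331 with an estimated correlation). Integrated stress response genes counted 10 rises, 2 falls and 9 not passing (11 and 2 when adjusted over the list alone) of 21, with STC2 (1.16) and CTH (0.90) against ALDH1L2 (-0.49) and PCK2 (-0.35; camera adjusted p = 0.000808, adjusted p = 0.0331 with an estimated correlation).

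A further 5 lists lay higher with camera's preset correlation and missed the threshold with an estimated one, and fry also put each of them up (adjusted p of at most 0.00013). Epithelial genes counted 14 rises, 3 falls and 3 not passing (15 and 3 when adjusted over the list alone) of 20. CLDN10 (2.90) and the splicing regulator ESRP1 (2.66) stood against CLDN4 (-0.72) and CLDN6 (-0.65; camera adjusted p = 4.41e-07, adjusted p = 0.0733 with an estimated correlation). In neural crest 9 rose, 1 fell and 5 did not pass (9 and 2 when adjusted over the list alone) of 15. SOX9 (2.38) and TFAP2A (2.17) stood against PAX3 (-0.51; camera adjusted p = 0.000158, adjusted p = 0.0531 with an estimated correlation). Cardiac and lateral mesoderm genes counted 11 rises, 1 fall and 6 not passing (11 and 1 when adjusted over the list alone) of 18. ISL1 (2.50) and TBX3 (2.24) stood against the myosin light chain MYL4 (-2.24; camera adjusted p = 0.000219, adjusted p = 0.101 with an estimated correlation). Trophoblast and amnion genes showed 8 rises, 1 fall and 13 not passing (8 and 2 when adjusted over the list alone) of 22. IGFBP3 (2448 ± 628 to 26619.9 ± 1094) and VGLL1 (2.63) stood against EPAS1 (-0.62; camera adjusted p = 0.0133, adjusted p = 0.101 with an estimated correlation). Of 12 cholesterol synthesis genes 8 rose, 0 fell and 4 did not pass (8 and 1 when adjusted over the list alone), led by HMGCS1 (0.74) and NSDHL (0.67; camera adjusted p = 0.0192, adjusted p = 0.176 with an estimated correlation).

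Camera called none of the remaining lists (adjusted p of 0.0717 or more). Fry put down the mouse GCNF target (adjusted p = 1.57e-07) and pluripotency (1.45e-06) lists. It put up those of DNA methylation (1.69e-05), hypoxia (0.000723), neural (0.00132), endoderm (0.00183) and WNT response (0.0102) genes. Pluripotency genes counted 7 rises, 10 falls and 13 not passing (8 and 10 when adjusted over the list alone) of 30 (camera adjusted p = 0.155): NR5A2 and KLF4 (1.05) rose and NANOG and PRDM14 fell most. Of 10 mouse GCNF targets 1 rose, 2 fell and 7 did not pass (1 and 2 when adjusted over the list alone). GDA (0.56) stood against NANOG and SOX2 (-0.38). Matrix and mesenchymal genes counted 7 rises, 8 falls and 11 not passing (7 and 8 when adjusted over the list alone) of 26, periostin, POSTN (1042 ± 209 to 10845 ± 571), and TWIST1 (1.45) against PDGFRB (-0.96) and COL6A3 (-0.82). WNT response genes counted 4 rises, 4 falls and 5 not passing (4 and 4 when adjusted over the list alone) of 13. SFRP1 (1.41) and WNT5A (0.97) stood against SP5 (-2.41) and NKD1 (-1.46). Neural genes counted 4 rises, 3 falls and 17 not passing (4 and 3 when adjusted over the list alone) of 24, the neurofilaments NEFM (278 ± 21.9 to 4811 ± 69.6) and NEFL (1.62) against ZIC2 (-1.54) and INA (-0.76). Of 21 endoderm and liver genes 5 rose, 1 fell and 15 did not pass (5 and 1 when adjusted over the list alone), the fibrinogen chains FGG (3.05) and FGB (2.60) against CXCR4 (-0.69; camera adjusted p = 0.0717). This list passed without replicate 1 or 2 of the RA-labelled arrays (0.0285 and 0.0332) and without replicate 3 of the Dox-labelled ones (0.0443). Endothelial and blood genes counted 3 rises, 1 fall and 13 not passing (3 and 1 when adjusted over the list alone) of 17. LMO2 (2.74) and HBE1 (2.24) stood against TIE1 (-2.03). In primitive streak 0 rose, 2 fell and 12 did not pass (0 and 1 when adjusted over the list alone) of 14, EOMES (-0.88) and CER1 (-0.95), the latter with overlapping arrays. Germ cell genes counted 2 rises, 0 falls and 17 not passing (2 and 0 when adjusted over the list alone) of 19, KIT (1.43) and PRDM1 (0.40). Of 15 p53 response genes 3 rose, 3 fell and 9 did not pass (4 and 4 when adjusted over the list alone). MDM2 (0.83) and GDF15 (0.67) stood against FAS (-0.94) and TP53I3 (-0.93). Hypoxia and glycolysis genes counted 8 rises, 4 falls and 6 not passing (8 and 5 when adjusted over the list alone) of 18. SLC2A3 (0.77) and PDK1 (0.75) stood against SLC2A1 (-1.27) and NDRG1 (-0.86). DNA methylation and corepressor genes counted 5 rises, 1 fall and 9 not passing (6 and 2 when adjusted over the list alone) of 15. MBD2 (1.15) and TET1 (0.63) stood against HDAC1 (-0.26). Median, mean and camera direction differed in sign for the primitive streak, endothelial, p53, WNT and DNA methylation lists.

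The ACTB ratio was 2.59 ± 0.290 in the RA-labelled and 2.33 ± 0.0580 in the Dox-labelled arrays, and the GAPDH ratio 1.35 ± 0.0817 and 1.46 ± 0.0230. Both groups were treated and no untreated day 6 cells were analysed here, so a difference has 2 possible sides.

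**Figure D2:**
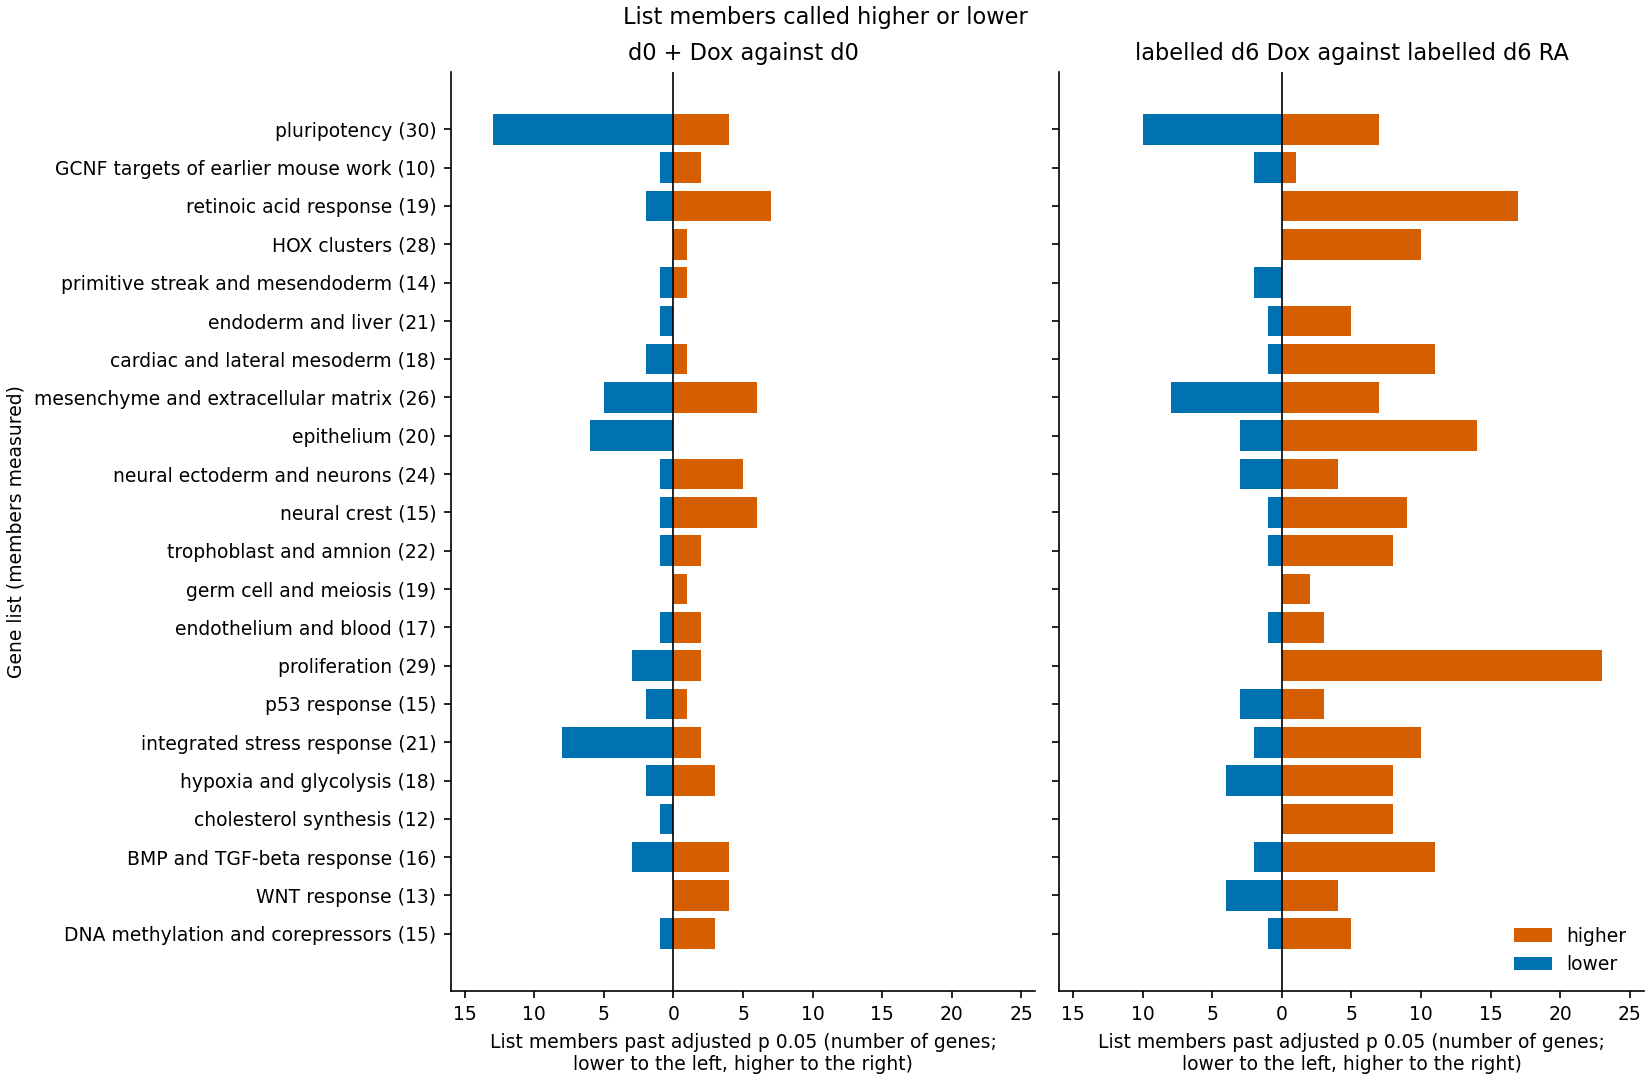
Number of members of each of 22 gene lists past adjusted p 0.05, higher to the right and lower to the left, with members measured in brackets; the left panel compares d0 with Dox against d0, the right panel Dox-labelled against RA-labelled day 6 arrays. Of 30 pluripotency genes 13 fell with Dox at d0, and 17 of 19 retinoic acid response genes were higher in the Dox-labelled arrays.

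The RA-labelled day 6 arrays were compared with d0 to give the change over differentiation, in which medium and time differed as well. Every measured pluripotency gene was lower and mesenchymal and matrix genes were higher. LEFTY1, an inhibitor of Nodal signalling, fell from 26512 ± 2796 to 348 ± 47.5 (-6.19 ± 0.14, adjusted p = 9.21e-10), and the collagen crosslinking enzyme LOX rose from 422 ± 19.4 to 14532 ± 1051 (5.05 ± 0.10, adjusted p = 5.23e-10). In all 9993 genes were called (50.5%), 5007 higher and 4986 lower. After median centring the split was 5518 higher and 4284 lower, and over all probe sets 9699 higher and 11130 lower. Further large rises were GALNT16 (54.0-fold), thrombomodulin, THBD (log2 4.91), the adhesion receptor ADGRA2 (29.0-fold) and LOXL4, a relative of LOX (28.9-fold). Further falls were the noncoding RNA RMST (1459.7 ± 119 to 8.28 ± 4.05, to under the pseudocount), NODAL (log2 -5.79), the neuropeptide receptor NPY1R (-5.36) and FOXH1, a factor of Nodal signalling (-5.35).

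All 30 pluripotency genes fell (also 30 when adjusted over the list alone; camera adjusted p = 3.36e-18, adjusted p = 0.000152 with an estimated correlation). So did 6 of 10 mouse GCNF targets (6 when adjusted over the list alone; camera adjusted p = 0.00108, adjusted p = 0.0232 with an estimated correlation), among them NANOG (11672 ± 556 to 639.8 ± 46.0) and the DNA methyltransferase DNMT3B (-3.76). With all 30 pluripotency genes lower, the falls of members shared with that list add no separate result. Mesenchymal and matrix genes counted 24 rises, 1 fall and 1 not passing (24 and 1 when adjusted over the list alone) of 26, ZEB2 rising 19.9-fold and THY1 falling (-1.75; camera adjusted p = 1.09e-13, adjusted p = 0.0117 with an estimated correlation). Of 29 proliferation genes 2 rose, 27 fell and 0 did not pass (2 and 27 when adjusted over the list alone), cyclins CCND2 (1.02) and CCND1 (0.84) against MCM5 (-3.36) and BUB1B (-3.29; camera adjusted p = 4.29e-14, adjusted p = 0.0227 with an estimated correlation). In the p53 response 13 rose, 1 fell and 1 did not pass (13 and 1 when adjusted over the list alone) of 15, the cell cycle inhibitor CDKN1A going from 713 ± 199 to 7874 ± 376, with TP53INP1 (2.63) up and CCNG1 (-0.29) down (camera adjusted p = 8.07e-07, adjusted p = 0.0124 with an estimated correlation). The integrated stress response counted 17 rises, 1 fall and 3 not passing (17 and 1 when adjusted over the list alone) of 21. ALDH1L2 (3.99) and DDIT3 (2.74) stood against PHGDH (-0.54; camera adjusted p = 2.35e-07, adjusted p = 0.00736 with an estimated correlation). Retinoic acid response genes counted 12 rises, 3 falls and 4 not passing (12 and 3 when adjusted over the list alone) of 19 without a call for the list (camera adjusted p = 0.1): MEIS2 (3.04) and CRABP2 (2.13) rose, while RARRES2 (-5.20) and CYP26A1, at 4494 ± 252 at d0 and 271 ± 37.0 in arrays labelled retinoic acid (-3.98), fell.

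Further lists lost their call with an estimated correlation. Epithelial genes counted 3 rises, 14 falls and 3 not passing (3 and 14 when adjusted over the list alone) of 20. ESRP1 (-4.43) and CLDN7 (-3.25) stood against KRT8 (2.51) and CLDN4 (2.19; camera adjusted p = 0.000601, adjusted p = 0.166 with an estimated correlation). Cholesterol synthesis genes counted 1 rise, 9 falls and 2 not passing (1 and 10 when adjusted over the list alone) of 12. DHCR7 (-2.27) and INSIG1 (-2.26) stood against SC5D (0.46; camera adjusted p = 0.000336, adjusted p = 0.0628 with an estimated correlation). In the BMP and TGF-beta response 11 rose, 2 fell and 3 did not pass (11 and 2 when adjusted over the list alone) of 16. TGFB2 (3.85) and INHBA (2.79) stood against ID1 (-1.15) and PMEPA1 (-0.35; camera adjusted p = 0.00102, adjusted p = 0.0781 with an estimated correlation). DNA methylation and corepressor genes also lay lower, 4 rose, 9 fell and 2 did not pass (4 and 9 when adjusted over the list alone) of 15. TET2 (1.51) and MBD1 (0.91) stood against DNMT3B and TET1 (-2.96; camera adjusted p = 0.0471, adjusted p = 0.0966 with an estimated correlation); without replicate 1 of d0 or of the RA-labelled arrays the camera adjusted p was 0.0523 or 0.0545, and with the replicate block 0.0553.

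Camera called none of the remaining lists. Fry put up those of hypoxia (adjusted p = 2.23e-09), trophoblast (1.13e-06), HOX (8.40e-05), cardiac (0.000495) and neural (0.00883) genes and down those of primitive streak (1.06e-05), germ cell (5.16e-05) and WNT response (0.0155) genes, against camera's direction for the neural and WNT lists. HOX genes counted 7 rises, 0 falls and 21 not passing (5 and 0 when adjusted over the list alone) of 28, led by HOXB3 (2.52) and HOXB2 (1.83; camera adjusted p = 0.17). In endoderm and liver 6 rose, 3 fell and 12 did not pass (6 and 3 when adjusted over the list alone) of 21, the fetal serum protein AFP (3.74) against CXCR4 (-2.25; camera adjusted p = 0.377). Primitive streak genes counted 1 rise, 6 falls and 7 not passing (1 and 6 when adjusted over the list alone) of 14. LHX1 (1.58) stood against CER1 (-3.91; camera adjusted p = 0.1). Cardiac genes counted 7 rises, 2 falls and 9 not passing (7 and 2 when adjusted over the list alone) of 18. MEF2C (2.73) stood against ISL1 (-0.51; camera adjusted p = 0.134, and 0.0434 without replicate 3 of the RA-labelled arrays). Of 24 neural genes 5 rose, 5 fell and 14 did not pass (5 and 5 when adjusted over the list alone). STMN2 (3.32) stood against ZIC2 (-3.85; camera adjusted p = 0.969). Neural crest genes counted 8 rises, 4 falls and 3 not passing (8 and 4 when adjusted over the list alone) of 15. DLX2 (3.91) stood against FOXD3 (-2.93; camera adjusted p = 0.407). Of 22 trophoblast and amnion genes 7 rose, 3 fell and 12 did not pass (7 and 3 when adjusted over the list alone). KRT7 (4.06) stood against GABRP (-1.47; camera adjusted p = 0.17). Germ cell genes counted 2 rises, 4 falls and 13 not passing (2 and 4 when adjusted over the list alone) of 19. PRDM1 (1.76) stood against DAZL (-3.40; camera adjusted p = 0.17). In endothelium and blood 6 rose, 2 fell and 9 did not pass (6 and 1 when adjusted over the list alone) of 17. TIE1 (3.19) stood against KDR (-2.87; camera adjusted p = 0.406). Hypoxia and glycolysis genes counted 9 rises, 4 falls and 5 not passing (9 and 4 when adjusted over the list alone) of 18. NDRG1 (3.34) stood against PDK1 (-1.78; camera adjusted p = 0.1). WNT response genes counted 5 rises, 3 falls and 5 not passing (5 and 3 when adjusted over the list alone) of 13. WNT5B (3.23) stood against SFRP1 (-1.71; camera adjusted p = 0.949). The ACTB ratio was lower in the RA-labelled arrays (2.59 ± 0.290) than at d0 (3.24 ± 0.139). EST-derived NR6A1 signal was lower than at d0 (log2 -1.44 for the brightest) and that of 3 of the 4 mRNA-derived probe sets higher (3.09 for the most induced), the dim one not passing (-0.67).

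Dox-labelled day 6 arrays against d0 with Dox shared no array with the RA-labelled comparison. No label makes d0 with Dox the start of the day 6 cells, so this difference also holds any loss of the Dox effect at d0, as in GALNT16 (148 ± 18.7 at d0, 2694 ± 115 in d0 with Dox and 370.2 ± 13.4 in the Dox-labelled arrays). Pluripotency genes were again lower and mesenchymal genes higher, with retinoic acid and HOX genes higher as well, again against the label. NANOG dropped from 5468 ± 111 to 36.7 ± 3.28 (-6.70 ± 0.08, adjusted p = 3.65e-11), and CYP26B1 rose from 41.2 ± 17.4 to 5075 ± 346 (6.52 ± 0.23, adjusted p = 1.24e-08). In all 9120 genes were called (46.1%), 4392 higher and 4728 lower. After centring each array on its median the split was 5407 higher and 3606 lower, the median change of all genes moving from -0.03 to 0.11. Over all probe sets it was 8155 higher and 10906 lower. Further rises were KANK4 (60.7-fold), LOX (60.2-fold), CLSTN2, a synaptic cadherin (50.6-fold), and ALOX5AP, of leukotriene synthesis (50.3-fold). Further falls were the MIR302B precursor transcript (-6.84 on the log2 scale), LEFTY1 (-6.51), PRDM14 (2033 ± 155 to 14.1 ± 6.44, to under the pseudocount) and the protocadherin PCDH8 (log2 -6.00).

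Of 30 pluripotency genes 2 rose, 27 fell and 1 did not pass (2 and 28 when adjusted over the list alone), NR5A2 (2.47) and KLF4 (0.44) being the rises (camera adjusted p = 8.18e-16, adjusted p = 0.000273 with an estimated correlation). Mesenchymal and matrix genes counted 25 rises, 1 fall and 0 not passing (25 and 1 when adjusted over the list alone) of 26, POSTN going from 249 ± 14.1 to 10845 ± 571 and THY1 falling (-1.75; camera adjusted p = 8.18e-16, adjusted p = 0.00468 with an estimated correlation). BMP and TGF-beta response genes all rose, 16 of 16 (16 when adjusted over the list alone), INHBA from 44.3 ± 16.4 to 2714 ± 128 and TGFB2 from 429.6 ± 20.2 to 7808 ± 379 (camera adjusted p = 8.89e-10, adjusted p = 0.00532 with an estimated correlation). Retinoic acid response genes counted 16 rises, 0 falls and 3 not passing (17 and 0 when adjusted over the list alone) of 19 (camera adjusted p = 6.69e-11, adjusted p = 0.00117 with an estimated correlation). HOX genes counted 12 rises, 0 falls and 16 not passing (12 and 0 when adjusted over the list alone) of 28, HOXB3 (4.98) and HOXA2 (4.72) leading (camera adjusted p = 0.000415, adjusted p = 0.00855 with an estimated correlation). Integrated stress response genes counted 19 rises, 0 falls and 2 not passing (19 and 0 when adjusted over the list alone) of 21, ALDH1L2 (3.72) and STC2 (3.38) foremost (camera adjusted p = 3.37e-13, adjusted p = 0.000841 with an estimated correlation). The p53 response genes counted 13 rises, 1 fall and 1 not passing (13 and 1 when adjusted over the list alone) of 15. GDF15 (3.15) and CDKN1A (2.80) stood against CCNG1 (-0.30; camera adjusted p = 1.10e-08, adjusted p = 0.00468 with an estimated correlation). Proliferation genes counted 2 rises, 27 falls and 0 not passing (2 and 27 when adjusted over the list alone) of 29, with CCND2 (0.69) and CCND1 (0.67) against MKI67 (-2.71) and BUB1 (-2.66; camera adjusted p = 6.94e-13, adjusted p = 0.0156 with an estimated correlation). Cardiac and lateral mesoderm genes counted 11 rises, 2 falls and 5 not passing (11 and 2 when adjusted over the list alone) of 18. MEF2C (3.42) and PDGFRA (3.41) stood against MYL4 (-0.88) and BMP4 (-0.87; camera adjusted p = 0.000478, adjusted p = 0.0806 with an estimated correlation).

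Mouse GCNF targets counted 0 rises, 6 falls and 4 not passing (0 and 6 when adjusted over the list alone) of 10, NANOG and SOX2 (-3.74) falling most (camera adjusted p = 0.000971, adjusted p = 0.0156 with an estimated correlation). Members shared with the pluripotency list are counted in both. Of 18 hypoxia and glycolysis genes 11 rose, 2 fell and 5 did not pass (11 and 2 when adjusted over the list alone). NDRG1 (2.38) stood against HK2 (-1.08; camera adjusted p = 0.00404, adjusted p = 0.0222 with an estimated correlation). Cholesterol synthesis genes counted 0 rises, 9 falls and 3 not passing (0 and 9 when adjusted over the list alone) of 12, led by INSIG1 (-1.58) and DHCR7 (-1.33; camera adjusted p = 0.000478, adjusted p = 0.0457 with an estimated correlation). Of 15 DNA methylation and corepressor genes 2 rose, 9 fell and 4 did not pass (2 and 9 when adjusted over the list alone). TET2 (0.93) stood against DNMT3B (-3.69; camera adjusted p = 0.00124, adjusted p = 0.0156 with an estimated correlation). Trophoblast and amnion genes counted 10 rises, 4 falls and 8 not passing (10 and 4 when adjusted over the list alone) of 22. KRT7 (5.08) and IGFBP3 (4.51) stood against TFAP2C (-1.19; camera adjusted p = 0.0115, adjusted p = 0.0801 with an estimated correlation). The others did not pass with camera. Fry put up those of neural crest (adjusted p = 2.26e-05), endoderm (0.000117), neural (0.0029) and epithelial (0.0234) genes and down those of WNT response (1.26e-09), primitive streak (5.01e-05) and germ cell (0.00225) genes, against camera's direction for the neural and epithelial lists. In endoderm and liver 12 rose, 3 fell and 6 did not pass (12 and 3 when adjusted over the list alone) of 21, the endoderm factor GATA6 (5.07) against CXCR4 (-2.25; camera adjusted p = 0.056). Neural crest genes counted 8 rises, 4 falls and 3 not passing (8 and 4 when adjusted over the list alone) of 15. DLX2 (5.59) stood against EDNRB (-3.78; camera adjusted p = 0.056). With the replicate block the endoderm and neural crest lists passed (0.0489 and 0.0491), as they did without replicate 1 of d0 with Dox (0.0427 each), and the endoderm list also without replicate 3 of the Dox-labelled arrays (0.0455). Of 14 primitive streak genes 1 rose, 4 fell and 9 did not pass (1 and 4 when adjusted over the list alone). LHX1 (2.43) stood against CER1 (-4.05; camera adjusted p = 0.149). WNT response genes counted 3 rises, 8 falls and 2 not passing (4 and 8 when adjusted over the list alone) of 13. WNT5A (1.91) stood against DKK1 (-3.44; camera adjusted p = 0.149). In epithelium 6 rose, 12 fell and 2 did not pass (7 and 12 when adjusted over the list alone) of 20. KRT8 (3.52) stood against ESRP1 (-1.23; camera adjusted p = 0.332, Down with a median of -0.58 and a mean of 0.08). Germ cell genes counted 1 rise, 4 falls and 14 not passing (1 and 4 when adjusted over the list alone) of 19. PRDM1 (1.98) stood against DAZL (-5.13; camera adjusted p = 0.455, Down with a median of 0.02 and a mean of -0.44). Of 17 endothelial and blood genes 4 rose, 4 fell and 9 did not pass (4 and 5 when adjusted over the list alone). LMO2 (2.90) stood against KDR (-1.52; camera adjusted p = 0.599). Neural genes counted 5 rises, 7 falls and 12 not passing (5 and 7 when adjusted over the list alone) of 24. NEFM (3.99) stood against ZIC2 (-5.48; camera adjusted p = 0.958). The ACTB ratio was 2.33 ± 0.0580 in the Dox-labelled arrays and 3.86 ± 0.0111 in d0 with Dox.

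The changes with Dox at d0 were then set against those between the day 6 groups, which share no array. Across 19775 genes, which are not independent replicates, Pearson's r was -0.0243 and Spearman's rho -0.0602. Genes called in both included 333 that were higher in both and 176 lower in both, where independent lists would share 210.2 and 124. Another 448 rose with Dox at d0 but were lower in the Dox-labelled arrays and 326 had the opposite pattern, where independent lists would share 186 and 139.9. These counts take every gene as equally likely to be called, and every combination of directions exceeded them. The excess in the same direction therefore does not show a shared effect of Dox. GALNT16 (log2 4.05 and -4.51), SLITRK5 (2.93 and -3.03) and LIX1 (3.86 and -1.56) went opposite ways, whereas MEIS2 (3.12 and 2.64), PKDCC (3.42 and 2.58) and PRTG (2.99 and 1.82) rose in both.

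**Figure D3:**
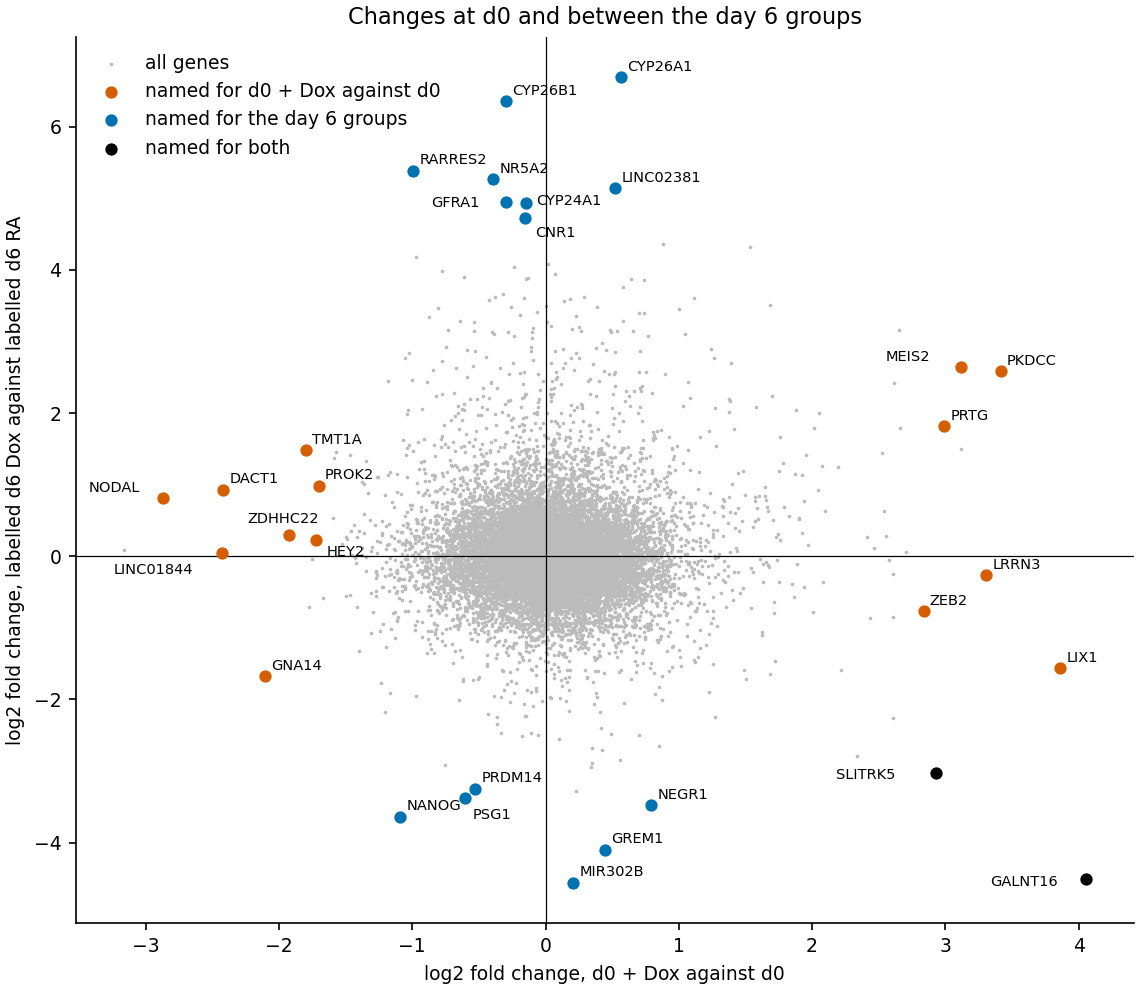
Log2 fold change of each gene with Dox at d0 (x axis) against that between Dox-labelled and RA-labelled day 6 arrays (y axis); grey points are all genes, coloured points the genes named for either comparison, black those named for both. GALNT16 and SLITRK5 lie at the lower right and MEIS2, PKDCC and PRTG at the upper right.

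Set against the change from d0 to the RA-labelled arrays, the Dox changes at d0 correlated across genes at r = 0.352 and rho = 0.373. Both comparisons use the d0 arrays, and unchanged groups sharing them gave a mean r of 0.501 in 100 simulations. The sharing alone fixes that value where no gene changes, so it is no yardstick for groups with many changed genes. Set beside it, the observed r neither shows nor excludes a shared change. The covariance was 0.136 against a simulated 0.0272, a difference of 0.108. Called genes shared 1003 rises and 700 falls, where independent lists would share 388 and 257, while 244 rose with Dox and fell at day 6 and 165 the reverse, against 386 and 258. Part of this excess may come from the shared d0 arrays. With these divided so that no array was shared (6 divisions, 1 array against the other two, added after the data were seen), r was 0.218 to 0.255 and the covariance 0.0994 to 0.106. NODAL (-2.87 and -5.79), NANOG (-1.09 and -4.16) and ZEB2 (2.84 and 4.31) went the same way in both, and OTX2 (0.82 and -2.73) and SFRP1 (1.95 and -1.71) opposite ways.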

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

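Of the tests in this part, those of the splits of the arrays and of all probe sets were planned and the others were chosen after the results were seen. Groups of 3 arrays were too small for a test of single arrays standing apart.

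RA-labelled arrays against d0 and Dox-labelled arrays against d0 with Dox went opposite ways for 436 genes, called in both comparisons and with a tested difference of the changes (limma, adjusted p under 0.05). They included 11 of the genes named as largest rises or falls with Dox at d0 or between the day 6 groups. By arithmetic this difference equals the change with Dox at d0 minus that between the day 6 groups. These genes were named for large changes there, so their values restate changes given above and are no further support. The difference of their changes, RA-labelled minus Dox-labelled on the log2 scale, was positive for GALNT16 (8.57), SLITRK5 (5.96), LIX1 (5.42), GREM1 (4.55), NEGR1 (4.27), LRRN3 (3.57) and PSG1 (2.77) and negative for RARRES2 (-6.38), CYP26A1 (-6.13), NR5A2 (-5.66) and DACT1 (-3.35). The count rests on d0 with Dox as a start that no label gives: with untreated d0 as the start of both, 168 of the 436 were called in opposite directions, 46 in the same direction and 222 not called for the Dox-labelled arrays. GALNT16, which lay lower in Dox-labelled arrays than in d0 with Dox (log2 -2.81), rose from untreated d0 in both (5.76 and 1.24), whereas CYP26A1 went opposite ways with either start (-3.98 and 2.72 from untreated d0).

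Both day 6 groups stood against their labels: retinoic acid genes were high in the Dox-labelled arrays, and 3 of the 4 mRNA-derived NR6A1 probe sets in the RA-labelled ones. Induced GCNF raising the retinoic acid genes stays open. For Dox-labelled against RA-labelled arrays the NR6A1 probe sets lay at -0.47 on the log2 scale (SD 1.52) as a mean of all 7. That mean decides nothing, since its probe sets opposed each other. The 4 mRNA-derived ones lay at -1.49 and the 3 EST-derived ones at 0.89. Against untreated d0 the mean of all 7 in the Dox-labelled arrays was -0.25 (SD 0.58). The most induced did not pass (0.11), 2 other mRNA-derived ones were higher (0.42 and 0.50) and the EST-derived ones were lower (-0.77, -0.64 and -0.54). All 7 were lower than in d0 with Dox (log2 -3.85 to -1.37), where stage and medium differed as well. No untreated day 6 cells were analysed here. Retinoic acid raising the cells' own GCNF gene stays open too. Retinoic acid response genes were mixed in RA-labelled arrays against d0. Of 19 measured, 12 rose and 3 fell, among the latter CYP26A1 (-3.98) and RARRES2 (-5.20). The mean of all 7 NR6A1 probe sets there was 0.22, which decides nothing either, since its probe sets opposed each other. The mRNA-derived ones lay at 1.54 and the EST-derived ones at -1.54. The part of the gene each reads is not given in the sources used here. An exchange of the day 6 labels may account for both and stays open. Counted were 181 genes at least 2-fold changed with Dox at d0 and called between the day 6 groups, outside the retinoic acid and HOX lists. Of these 45.3% changed the other way (45 of 120 rises and 37 of 61 falls), and of all 1283 genes called in both 60.3% did. This share cannot decide, since the day 6 groups also differ in retinoic acid and the share moved with the set of genes. No array was regrouped.

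Pluripotency genes were lower with Dox at d0, and a lower share of undifferentiated cells would lower those that such cells express most. Yet 4 members rose with Dox at d0 and fell from d0 to the RA-labelled arrays: OTX2 (log2 0.82), SFRP2 (0.41), SOX2 (0.35, missing the threshold without any single array) and TRIM71 (0.28, named after its value was seen). That argues against admixed cells like those of the RA-labelled day 6 arrays as the whole cause, not against another cell type that expresses these genes. Dox itself stays open, since 0 arrays held Dox-treated cells without the construct, and so does induced GCNF, which cannot be told apart from it here. The shared POU5F1-family probe set, outside the gene tests because it reads 4 genes, fell as well (-0.81).

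Outside the gene tests, 384 of 13522 probe sets without a single gene name, control probe sets aside, were called with Dox at d0 (214 higher, 170 lower), a share of 2.84% against 6.79% of the other probe sets.

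With 3 arrays against 3 there are 10 splits of the 6 arrays, too few for a share under 0.05. Refitted on 2 groups, 1 split, the real one, gave as many genes in each comparison: 1522 for d0 with Dox against d0, 4416 for the day 6 groups, 9230 for RA-labelled against d0 and 8915 for Dox-labelled against d0 with Dox, with 0 as the highest of the other splits each time.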

How the results depend on the processing

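All alternatives were planned. Counts of called genes stayed within 1.5 times the reported ones, except as follows. On the 6 arrays alone, with fewer degrees of freedom, d0 with Dox against d0 gave 1522 genes. Requiring at least 2-fold gave 365, 1144, 4219 and 3430 in the order of the 4 comparisons in the report, and testing all 54675 probe sets gave 8471, 20829 and 19061 in the last 3. Leaving out each array gave 1786 to 2323, 4043 to 4490, 9272 to 9520 and 8296 to 8370. Same-numbered arrays deviated together weakly if at all (correlations of -0.00843 to 0.0483). Each array correlated best with its own number in 2, 3, 4 and 6 of 6 cases, so whether the numbers pair the samples was left unsettled. With the replicate block 2296, 4901, 9916 and 8987 genes were called. The correlation of the Dox changes with those between the day 6 groups was -0.0676 among brighter genes and -0.0317 to -0.0128 without an array, and that with the change to RA-labelled arrays 0.334 to 0.375; the cause was not tested. With the mean of all its probe sets, NR6A1 turned to -0.47 between the day 6 groups and 0.22 from d0 to RA-labelled arrays, since its probe sets oppose each other, and MBD2 to 0.0238 from d0 with Dox to Dox-labelled arrays. Across all named-gene values 4492 kept direction and side of the threshold, 203 kept direction only, and 3 turned. Of list tests 911 were the same, 17 lost and 36 gained the threshold, and 4 turned under fry: neural genes (adjusted p = 0.00883) and WNT genes (0.0155) for RA-labelled against d0, and epithelium (0.0234) and neural genes (0.0029) for Dox-labelled against d0 with Dox; fry weighs members by their own spread, and the cause was not tested. Signals under the pseudocount of 16, 23.1% to 26.5% of probe sets, limit what can be read of dim genes.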

Other observations

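The tests of the integrated stress response list were planned, but setting them against an effect of doxycycline, and the division of the BMP and TGF-beta response list, were chosen after the results were seen.

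The BMP and TGF-beta response list held members of opposite movement with Dox at d0. Divided into genes known to be induced by BMP and by TGF-beta, 4 of 9 BMP members rose (ID4, ID3, ID2 at 1.41 and MSX2) and 0 fell, in limma at adjusted p under 0.05, while ID1 (-0.11), SMAD6 (-0.21) and BAMBI (-0.19) did not pass. Of 7 TGF-beta members 3 fell (PMEPA1, SMAD7 and SKIL at -1.02) and 0 rose. ID2, SKIL, ID1, SMAD6 and BAMBI were named after their values were seen. The medians differed by 0.70 (exact permutation p = 0.0223), but the members had been seen before they were divided, so this p decides nothing.

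Doxycycline is known to inhibit mitochondrial translation, which could raise integrated stress response genes whatever GCNF does. With Dox at d0 the list instead lay lower (camera adjusted p = 0.00772, Down also with fry, against adjusted p = 0.0964 with an estimated correlation), with ATF3 (-0.59) and STC2 (-0.77) lower and DDIT4 (0.77) and SLC7A11 (0.48) higher. The list as a whole did not go up, but this effect of Dox stays open, since the downward call depended on the correlation used and a rise with Dox masked by a fall with GCNF cannot be told apart here.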
